A study of Mus musculus with 15 samples.

How the data were processed

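RNA was measured in cells of the ventral midbrain of Pitx3-GFP mice, in which green fluorescent protein (GFP) reports the activity of Pitx3, the gene of a dopamine neuron transcription factor, after fluorescence-activated cell sorting. One experiment compared GFP+ with GFP− cells at embryonic day 14 (E14), with 3 libraries of each. A separate time series held GFP+ cells at E14, embryonic day 16 (E16) and the day of birth (P0), with 3 libraries per age, for 15 samples in 5 groups. The submitters state that midbrains of 3 litters were used and that each group had 3 replicates. They do not say that each replicate came from its own litter, so the p-values measure the spread between these samples, part of which may be technical. Total RNA was extracted with the miRNeasy micro kit, ribosomal RNA was removed with Ribo-Zero, and libraries were made with ScriptSeq v2. This preparation keeps RNAs without a poly(A) tail, among them circular RNAs (circRNAs), which are closed loops counted from reads across a back-splice junction.

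The authors deposited normalized reads, here treated as a signal value, per gene and per circRNA, with each library divided by 1 scaling factor. The submitters' processing notes name Trim Galore, TopHat2, DESeq2, GRCm38 and mm10 without versions. The circRNA caller and its filters, the read counter and the use of strand were not given in the sources used here, so reads of genes that overlap on opposite strands could not be told apart. Per the file headers, the authors also deposited log2 fold changes with standard errors, and p-values (p_value) with adjusted p, made by the authors with their test for each comparison. Values taken from those columns are named as the authors' deposited table and carry no replicate SD, and an adjusted p given there as NA was kept as NA. The columns of the sorted circRNA table in hand covered the GFP− libraries, so circRNAs in GFP+ against GFP− cells were taken from the authors' deposited table and not refitted. A table's circRNA number is its own abundance order and no coordinates came with it, so circRNAs were not matched between the sorted table and the time series. Reads within an exon count toward a gene whether the RNA was linear or circular, so the gene values called linear here include reads of circles.

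In each library the deposited values were spaced by a constant step, and dividing by that step gave whole numbers within 0.1 for 100% of values. These recovered reads gave the depth. The lowest value was 38 reads in the time series gene table and 2 in the circRNA tables, so there the step was taken from the spacing between values and not from a value of 1 read. Reads of those tables were not accepted as counts for a count model, and the circRNA totals and all values per 1000000 gene reads rest on these steps. The sorted libraries held 17369191 to 22374153 reads over 21566 genes, and the time series libraries 17910017 to 33386535 over 10781 genes. The lowest mean among the latter was 107 normalized reads, so that table is a part of each library and genes of low abundance were not analysed here. The time series libraries held 11196 to 33061 circRNA reads over 7528 circRNAs and the GFP− sorted libraries 10498 to 16509 over 3927, with 2 reads as the lowest value above 0. Reads carried no molecular identifiers, so floors cover counting error alone. A fold against a group with 0 reads was computed against a floor of 3 reads over the group. No circRNA value of 1 read appears, so a 0 can stand for 1 read in a library. Such a fold is therefore a value at the floor and not a lower bound.

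Genes and circRNAs were tested with limma-trend (limma 3.58.1, R 4.3.3; two-sided) on log2(normalized reads + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes needed a mean of at least 5 normalized reads and circRNAs a mean of at least 2. The sorted libraries were fitted on their own, and the 9 time series libraries in a single fit that shared the estimate of the spread. The time series fit gave E14 to E16, E16 to P0 and E14 to P0, a moderated F test of any change over the 3 ages, and a contrast of the change after E16 against the change before it. For each circRNA whose host gene was in the gene table, the log2 ratio of circRNA to host was fitted in the same way. The sum of circRNA reads per 1000000 gene reads was compared by exact permutation of the libraries, two-sided. Because the factors of the circRNA and gene tables differed, this ratio used recovered reads, a choice made after the data were seen. Gene positions come from GENCODE M21 on GRCm38.

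The groups, the tests, the thresholds, the gene lists, the rule for named genes and most alternative settings were fixed before the data were examined. The rule named Pitx3, Th, Slc6a3, Nr4a2 and Rmst where measured. It added the 5 genes with the largest change in each direction among those past the threshold with a mean of at least 50 and no overlap between the replicates, and up to 3 members per direction of each list with the smallest p. For circRNAs it named those of Rmst and the 5 with the largest change in each direction past the threshold, or the 3 with the smallest p where fewer than 3 passed. Some genes and circRNAs that the rule named are not reported here. The 22 lists held genes of dopamine handling, midbrain dopamine transcription factors, radial glia and progenitors, cell division, GABAergic neurons, other neurons, the oligodendrocyte lineage, astrocytes, microglia, blood vessels, erythroid cells, migration and axon guidance, synapses, ion channels, long non-coding RNAs (lncRNAs), splicing and RNA editing, dissociation stress, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, neurotrophic signalling and known hosts of brain circRNAs. Lists were tested with limma camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list's genes move at all, were run beside it.

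Alternatives covered the pseudocount (4 for genes, 0.5 for circRNAs), the filter, the scaling (edgeR 4.0.16 TMM, equal circRNA totals, or, for the ratio, circRNA reads on the gene table's scale), the replicate number as a block, and leaving out each library in turn. edgeR quasi-likelihood and DESeq2 1.42.0 were also run on the recovered reads of the sorted gene table. The columns of the sorted gene table number the libraries 1 to 3 in both fractions. Deviations from the group means correlated at 0.645, 0.357 and 0.234 between GFP+ and GFP− libraries of the same number. Between libraries of different numbers they correlated at -0.542 to 0.395. The numbers were taken to pair the libraries, each same-numbered pair being over 0.1, but the values set apart only the pair of number 1. Deviations within a group cancel out, so that pair by itself raises the correlations among numbers 2 and 3. There the crossed pairs, at 0.184 and 0.395, were as close as the same-numbered ones. The GFP− library of number 3 and the GFP+ library of number 2 were closer to each other (0.395) than to their own numbers. The sample descriptions give both fractions the same set of numbers, which points to pairs of GFP+ and GFP− samples. The labels do not tie the columns to those samples. Which columns form a pair rests on the column numbers, and for number 1 also on these values. The main fit of the sort ignores the pairing, and the fit with the numbers as a block was added after the data were seen. Leaving out 1 library leaves 2 in its group, which are assumed to vary like the others. The pipeline was tested on simulated data of the same depth with 200 changed genes or circRNAs. The simulation gave all rows of a table the same spread between replicates beyond counting error. It had no outlying library and no deviations shared between libraries, so its rates need not hold for the data. In the simulated sort 59.4% of 1.5-fold, 81.8% of 2-fold and 97.0% of 4-fold changes were called, with 3.11% of calls false. In the simulated series of genes 100% were called at each fold with 6.10% of calls false. For circRNAs none of the 1.5-fold or 2-fold changes was called (0%), and 29.2% of the 4-fold changes were, with 5% of calls false. For ratios 0%, 1.64% and 33.3% were called, with 4.17% of calls false. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.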

Results

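At E14, the sorted GFP+ cells held far more RNA of the genes that make, store and recapture dopamine than the GFP− cells did. Th, the rate-limiting enzyme of dopamine synthesis (chromosome 7, 142892752 to 142931128), stood at 90.0 ± 17.7 normalized reads in GFP− and 8559 ± 850 in GFP+ cells (mean ± SD, n = 3 libraries per group), a log2 fold change of 6.57 (SE 0.13). Slc6a3, the dopamine transporter (chromosome 13, 73536747 to 73578672), was higher by a log2 fold change of 7.85 (SE 0.25). Aldh1a1, an aldehyde dehydrogenase of ventral dopamine neurons (chromosome 19, 20492715 to 20643465), and Chrna6, a nicotinic receptor subunit, were higher by 7.80 (SE 0.19) and 7.99 (SE 0.20). Gch1, which starts the synthesis of the Th cofactor tetrahydrobiopterin, was higher by 4.79 (SE 0.11). Pitx3 itself (chromosome 19, 46135685 to 46148326) was at 7.40 ± 1.19 in GFP− and 1106 ± 216 normalized reads in GFP+ cells, but it is the gene whose reporter was sorted on and so no independent measure of the sort. Of 20 tested genes of dopamine handling, 14 were higher and 3 lower in GFP+ cells (14 and 4 adjusted over the list alone; camera adjusted p = 5.2e-10, and adjusted p = 0.0986 with an estimated correlation). The 3 lower genes were Sncg, a synuclein, Maoa, which breaks down monoamines, and Spr, the last enzyme of tetrahydrobiopterin synthesis, with log2 fold changes of -2.31, -0.72 and -1.05.

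**Figure D1:**
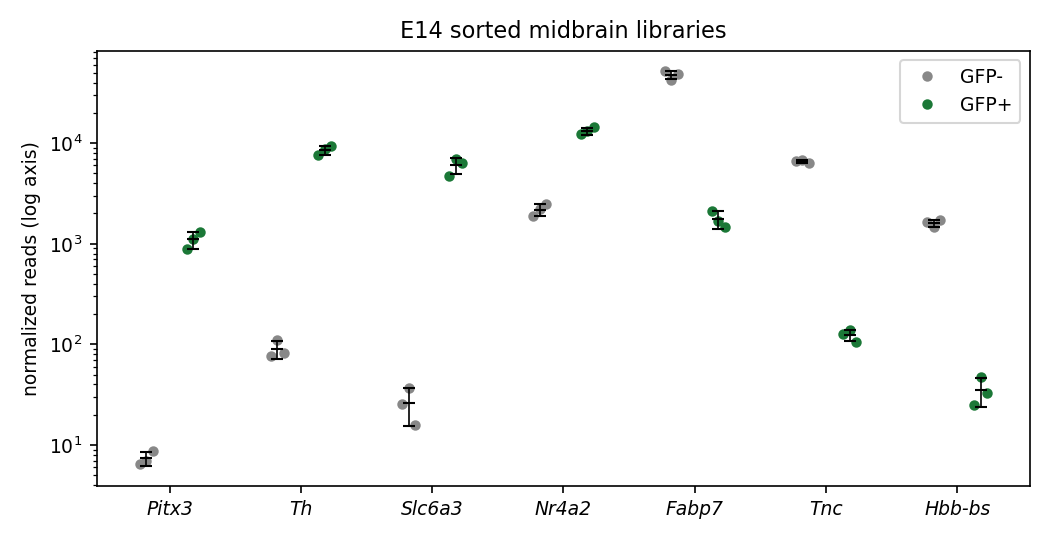
Normalized reads (log axis) of Pitx3, Th, Slc6a3, Nr4a2, Fabp7, Tnc and Hbb-bs in each of the 3 GFP− and 3 GFP+ libraries at E14, with black bars for the mean ± SD. The first 4 genes were higher in every GFP+ library than in any GFP− library, and Fabp7, Tnc and Hbb-bs were lower.

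Transcription factors of midbrain dopamine neurons were also higher in GFP+ cells. Nr4a2 (Nurr1), needed for the dopamine phenotype (chromosome 2, 57106830 to 57124003), stood at 2181 ± 301 in GFP− and 13236 ± 1072 normalized reads in GFP+ cells (log2 fold change 2.61, SE 0.11; n = 3 per group). En2, a homeobox gene of the midbrain, was higher by 3.49 (SE 0.10). Of 18 tested factors, 14 were higher and 2 lower (16 and 2 adjusted over the list alone; camera adjusted p = 2.07e-13, and adjusted p = 0.0765 with an estimated correlation). The 2 lower ones were Onecut2 and Nr4a3, at log2 fold changes of -0.87 and -0.86. Among neurotrophic receptors and signals, Ret and Gfra1, which together bind the dopamine neuron survival factor GDNF, were higher by 4.14 (SE 0.16) and 2.66 (SE 0.09). That list split evenly, with 9 of 22 higher and 9 lower (9 and 9 adjusted over the list alone; camera adjusted p = 0.27), and Fgfr2, Tgfb2 and Smad3 were among the lower ones.

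Genes of dividing cells, progenitors and glia were lower in GFP+ cells. Fabp7, a fatty acid binding protein of radial glia, stood at 47842 ± 4860 in GFP− and 1762 ± 344 normalized reads in GFP+ cells (log2 fold change -4.78, SE 0.13; n = 3 per group). Sox2, a stem cell transcription factor, was lower by a log2 fold change of -3.90 (SE 0.11) and Mki67, a proliferation marker, by -3.54 (SE 0.15). The extracellular matrix gene Tnc had the lowest log2 fold change among the named genes, -5.73 (SE 0.10). Of 24 tested radial glia and progenitor genes, 22 were lower and 1, the secreted signal Wnt5a, was higher by 2.11 (1 higher and 22 lower adjusted over the list alone; camera adjusted p = 1.03e-17, and adjusted p = 0.0765 with an estimated correlation). Of 30 cell division genes, 29 were lower and 0 higher (30 and 0 adjusted over the list alone; camera adjusted p = 1.84e-22, and adjusted p = 0.0765 with an estimated correlation). Of 14 astrocyte genes 10 were lower, with Aldh1l1 at -4.62, and 1 higher, the glutamate transporter Slc1a2 at 0.55 (10 and 1 adjusted over the list alone; camera adjusted p = 2.37e-07, and adjusted p = 0.104 with an estimated correlation). Of 14 genes of the oligodendrocyte lineage 7 were lower, among them Olig2 and Pdgfra, and 0 higher (7 and 0 adjusted over the list alone; camera adjusted p = 0.000524, and adjusted p = 0.374 with an estimated correlation).

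Genes of other neurons and of cells from outside the neural lineage were lower as well. Of 20 tested GABAergic genes 17 were lower, among them the transcription factors Dlx1, Tal1 and Lhx5 at log2 fold changes of -4.65, -4.46 and -4.16. The 2 higher ones included Slc32a1, the vesicular GABA transporter, at 1.16 (17 and 2 adjusted over the list alone; camera adjusted p = 1.04e-11, and adjusted p = 0.0765 with an estimated correlation). Of 17 genes of glutamatergic, cholinergic and serotonergic neurons 15 were lower, among them Barhl1 and Isl1, and 0 higher (15 and 0 adjusted over the list alone; camera adjusted p = 2.82e-10, and adjusted p = 0.0765 with an estimated correlation). All 9 erythroid genes tested were lower, with the haemoglobin gene Hbb-bs at -5.53 (9 adjusted over the list alone; camera adjusted p = 1.19e-11, and adjusted p = 0.0986 with an estimated correlation). Of 16 microglial genes 15 were lower, with Csf1r at -3.25, and 1 was higher, the macrophage mannose receptor Mrc1 at 2.35 (15 and 1 adjusted over the list alone; camera adjusted p = 5.75e-09, and adjusted p = 0.0986 with an estimated correlation). Of 20 blood vessel genes 18 were lower, with Pdgfrb at -4.08, and 0 higher (18 and 0 adjusted over the list alone; camera adjusted p = 9.28e-07, and adjusted p = 0.0986 with an estimated correlation).

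Neuronal gene groups moved in both directions between the sorted fractions. Of 35 ion channel genes 15 were higher, among them Kcnip4, a subunit of potassium channels, and Kcnd3, a potassium channel, at log2 fold changes of 2.46 and 1.87, and 4 were lower (17 and 6 adjusted over the list alone; camera adjusted p = 0.012, and adjusted p = 0.281 with an estimated correlation). With the column numbers of the libraries as a block 19 were higher and 9 lower (19 and 10 adjusted over the list alone; camera adjusted p = 0.00359, and adjusted p = 0.454 with an estimated correlation). Of 45 synaptic genes 11 were higher, among them the glutamate receptor subunit Gria3 at 2.22 (SE 0.10) and the neurexin Nrxn3 at 1.74 (SE 0.10), and 8 lower (13 and 9 adjusted over the list alone; camera adjusted p = 0.132). With the block 19 were higher and 13 lower (19 and 13 adjusted over the list alone; camera adjusted p = 0.0919). Of 48 genes of migration and axon guidance 16 were higher, among them the ephrin receptor Epha5 and the chemokine receptor Cxcr4 at 1.71 and 1.54, and 13 were lower, among them Sema3c and Epha3 at -2.33 and -2.10 (17 and 16 adjusted over the list alone; camera adjusted p = 0.25; the list's mean was -0.05 and its median 0.16). Of 34 splicing and RNA editing genes 9 were higher and 7 lower (9 and 7 adjusted over the list alone; camera adjusted p = 0.205), with Adarb2 at 1.61 and Qk at -2.65. The block gave 17 higher and 7 lower (17 and 7 adjusted over the list alone; camera adjusted p = 0.158). Of 33 known circRNA host genes 12 were higher and 4 lower (13 and 4 adjusted over the list alone; camera adjusted p = 0.0286, and adjusted p = 0.227 with an estimated correlation). Of 24 genes of dissociation stress 8 were lower, among them the immediate early genes Fos and Egr1 at -2.33 and -2.05, and 1 was higher, Klf4 at 2.74 (10 and 1 adjusted over the list alone; camera adjusted p = 0.0247, and adjusted p = 0.222 with an estimated correlation). With the block 13 were lower and 2 higher (13 and 2 adjusted over the list alone; camera adjusted p = 0.0390, and adjusted p = 0.397 with an estimated correlation).

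The imprinted lncRNAs Rian, Mirg and Peg13 were higher in GFP+ cells, by log2 fold changes of 0.98, 1.12 and 1.10 (SE 0.12, 0.12 and 0.10). The lncRNA Dlx6os1, beside the interneuron gene Dlx6, and the imprinted lncRNA H19 were lower by -4.78 (SE 0.23) and -1.75 (SE 0.10). Of 30 tested neural lncRNAs 7 were higher and 9 lower (7 and 9 adjusted over the list alone; camera adjusted p = 0.428). With the block the split turned to 14 higher and 10 lower (14 and 12 adjusted over the list alone; camera adjusted p = 0.962). Of all 1813 lncRNA genes tested 193 were higher and 176 lower without the block. For genes of energy metabolism and translation the calls depended on the pairing of the libraries. Of 44 oxidative phosphorylation genes 2 were lower, Ndufa4 among them (1 adjusted over the list alone; camera adjusted p = 0.137). With the block 11 were lower (9 adjusted over the list alone; camera adjusted p = 0.0916). Of 44 ribosomal protein genes 1 was lower (0 adjusted over the list alone; camera adjusted p = 0.0256, and adjusted p = 0.669 with an estimated correlation). The block gave 15 lower (12 adjusted over the list alone; camera adjusted p = 0.00718, and adjusted p = 0.697 with an estimated correlation). Of 14 mitochondrially encoded genes limma called 0 (0 adjusted over the list alone; camera adjusted p = 0.374), with mt-Nd1 at 9261 ± 185 in GFP− and 8115 ± 2527 normalized reads in GFP+ cells (log2 fold change -0.24, limma adjusted p = 0.350, and 0.0338 with the block). Over all 18260 genes tested, limma called 5599 at adjusted p of 0.05, 2313 higher and 3286 lower in GFP+ cells, of which 775 and 2042 differed by at least 2-fold. With the block it called 8466, 4149 higher and 4317 lower. The replicates did not overlap for 44.1% of genes, against 10% by chance. Rmst had no row in this gene table and was not analysed here as a gene.

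CircRNAs of the sorted fractions come from the authors' deposited table, which held an adjusted p for 958 of 3927 circRNAs and NA for 2969. Of those, 11 passed 0.05, 10 higher and 1 lower in GFP+ cells. The smallest p belonged to circ_00004_Rmst, from Rmst, a long non-coding RNA gene known from the developing midbrain, at a log2 fold change of 0.99 (SE 0.13, adjusted p = 1.58e-11). Its GFP− libraries held 163 ± 18.8 normalized reads (n = 3), and the other 7 Rmst circRNAs with an adjusted p did not pass, the nearest being circ_00018_Rmst at 0.36 (adjusted p = 0.762). Of the others, circ_00041_Lmx1a and circ_00272_Bnc2, from 2 transcription factor genes, were higher by 1.90 (SE 0.31, adjusted p = 3.02e-07) and 4.34 (SE 0.98, adjusted p = 0.00226). circ_00147_AF529169 was higher by 4.22 (SE 0.76). circ_00706_Gm21949, at 0 reads in GFP− cells, was higher by 5.52 (SE 1.54, adjusted p = 0.0317) in the authors' deposited table. Its GFP+ mean was derived here from the authors' mean over all sorted libraries and the GFP− mean. That derived mean, 7.72 normalized reads, was 8.30-fold the floor of 3 reads. The single circRNA that was lower, circ_00190_Plce1, came from a phospholipase gene, at -2.16 (SE 0.61, adjusted p = 0.0348). Another 4, named after their values were seen, were circ_00095_Pde5a, circ_00013_Fat3, circ_00066_Gfra1 and circ_00057_Pbx3, higher by 1.75, 0.65, 1.87 and 1.29. In the authors' separate deposited values for genes, the hosts Lmx1a, Bnc2, Gfra1 and Pbx3 were higher too, by 2.14, 4.05, 2.66 and 1.64, and Plce1 was lower by -1.36. The hosts AF529169, Gm21949 and Fat3 were higher by 3.07, 2.62 and 0.60. Pde5a was higher by 0.46, against 1.75 for its circRNA.

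From E14 to P0 the GFP+ cells gained RNA of 12 of 18 genes of dopamine handling, the transporter among them, and lost RNA of the transcription factors that specify these neurons. Aldh1a1 rose from 20609 ± 3177 to 167996 ± 14339 normalized reads (n = 3 per age; log2 fold change 3.04, SE 0.12) and Slc6a3 from 10187 ± 858 to 30141 ± 11068 (2.83-fold by the fitted mean logs). Maoa, which breaks down monoamines, and Chrnb3, a nicotinic receptor subunit, rose by 1.69 (SE 0.09) and 1.98 (SE 0.13). Th was at 9381 ± 360 at E14 and 10420 ± 1423 at P0 (0.14, SE 0.12, limma adjusted p = 0.341). Ddc, which makes dopamine from L-DOPA, and Dlk1, a Notch ligand relative, fell by 0.69 (SE 0.10) and by 1.49 (SE 0.11) on the log2 scale. Of 18 genes of dopamine handling 12 rose and 3 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.00322, and adjusted p = 0.474 with an estimated correlation). Nr4a2 fell from 11197 ± 90.9 to 7114 ± 610 normalized reads (-0.66, SE 0.08), Pitx3 from 818 ± 59.0 to 381 ± 19.1 (-1.10, SE 0.11), and Foxa2, Lmx1a and Ebf3 by log2 fold changes of -1.09, -0.93 and -1.36. Of 17 of these transcription factors 15 fell and 0 rose (15 and 0 adjusted over the list alone; camera adjusted p = 3.73e-07, and adjusted p = 0.187 with an estimated correlation).

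**Figure D2:**
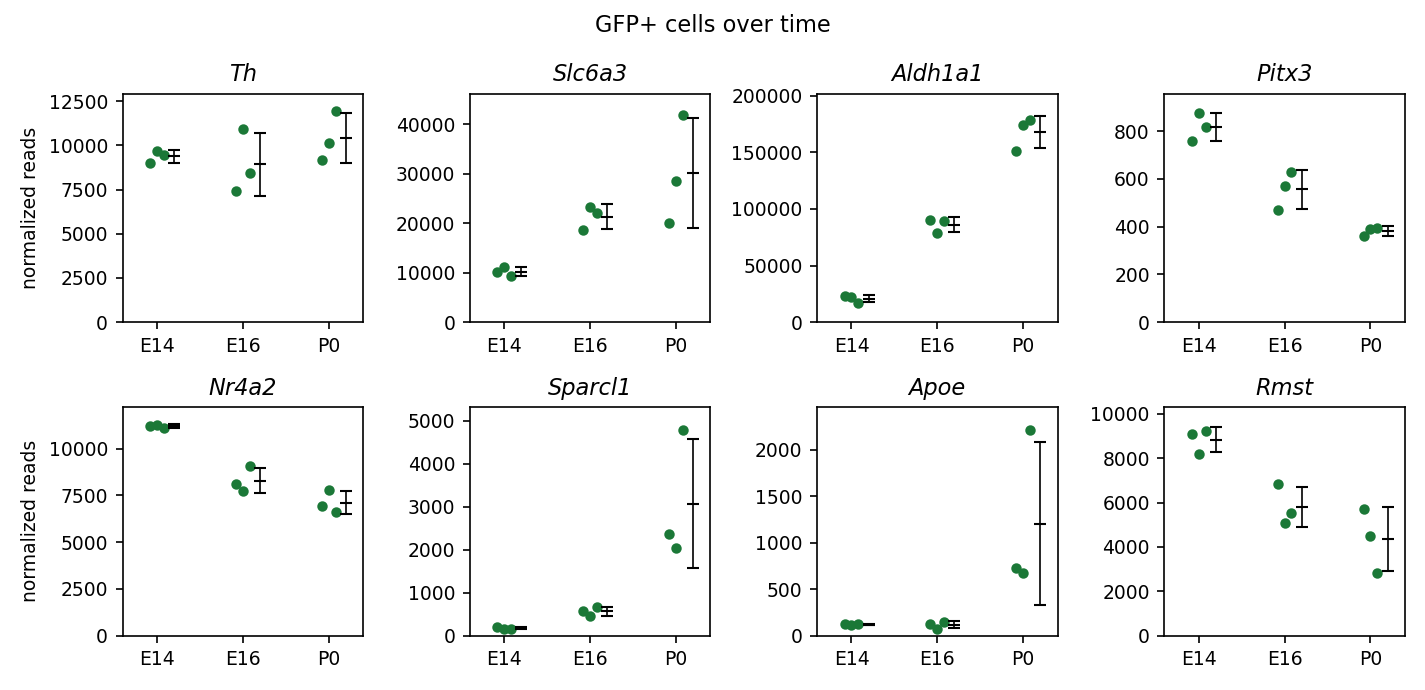
Normalized reads of Th, Slc6a3, Aldh1a1, Pitx3, Nr4a2, Sparcl1, Apoe and Rmst in GFP+ cells at E14, E16 and P0, each point a library (3 per age) and bars the mean ± SD. The mean of Aldh1a1 rose from 20609 at E14 to 167996 at P0, and the means of Th stayed between 8927 and 10420. The means of Pitx3, Nr4a2 and Rmst were lowest at P0. For Nr4a2 and Rmst the single libraries of E16 and P0 overlapped.

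Genes of synapses and excitability rose from E14 to P0. Sv2c, a synaptic vesicle protein of dopamine terminals, rose from 606 ± 158 to 6249 ± 1836 normalized reads (log2 fold change 3.35, SE 0.19; n = 3 per age), and Syp, another vesicle protein, by 1.24 (SE 0.08). The cation channels Trpc6, Scn2a and Nalcn rose by 3.08 (SE 0.14), 1.12 (SE 0.08) and 1.16 (SE 0.09), and the neurotrophin Ntf3 by 3.02 (SE 0.24). Of 44 synaptic genes 34 rose and 3 fell (35 and 3 adjusted over the list alone; camera adjusted p = 1.69e-10, and adjusted p = 0.187 with an estimated correlation). Of 32 ion channel genes 24 rose and 1, Cacna2d3, fell (24 and 1 adjusted over the list alone; camera adjusted p = 2.19e-07, and adjusted p = 0.301 with an estimated correlation). Of 17 neurotrophic genes 9 rose and 4 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.213), with Igf1 and Fgfr2 up by 1.65 and 1.56 and Gfra1 and Igf1r at -0.78 and -0.87.

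Single genes of axon guidance and cell cycle exit, and most ribosomal protein genes, fell over the same time. The guidance protein Draxin fell from 2297 ± 145 to 269 ± 73.4 normalized reads (log2 fold change -3.13, SE 0.16; n = 3 per age), and Cdkn1c, an inhibitor of the cell cycle, from 4833 ± 925 to 585 ± 155 (-3.06, SE 0.17). Pdzrn3, a ubiquitin ligase, Sinhcaf, a corepressor subunit, and Fzd10, a Wnt receptor, fell by log2 fold changes of -3.14, -3.01 and -2.58. Of 45 genes of migration and axon guidance 10 rose, among them Unc5c and Sema5a at 1.72 and 1.64, and 20 fell, among them Epha3, Ephb2 and Robo1 at -0.88, -0.80 and -0.77 (11 and 20 adjusted over the list alone; camera adjusted p = 0.337). Of 44 ribosomal protein genes 38 fell, with Rpl18 at -0.81, and 0 rose (39 and 0 adjusted over the list alone; camera adjusted p = 1.29e-07, and adjusted p = 0.439 with an estimated correlation). Of 12 mitochondrially encoded genes 10 fell, with mt-Nd4 at -0.54, and 0 rose (10 and 0 adjusted over the list alone; camera adjusted p = 0.00909, and adjusted p = 0.439 with an estimated correlation). Mitochondrially encoded genes held 0.251% to 0.363% of reads at P0 and 0.400% to 0.497% at E14. Of 32 splicing and RNA editing genes 20 fell, among them Rbfox2 and Khdrbs3 at -0.64 and -0.69, and 4 rose, among them Adarb1 and Rbfox3 at 0.55 and 0.68 (20 and 4 adjusted over the list alone; camera adjusted p = 0.0125, and adjusted p = 0.386 with an estimated correlation).

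Over all 10781 genes tested, limma called 6003 between E14 and P0, 2702 higher and 3301 lower at P0, of which 578 and 262 changed by at least 2-fold. The replicates did not overlap for 65.2% of genes, against 10% by chance. The moderated F test called 6432 genes over the 3 ages. Rescaling by TMM moved the split to 3014 higher and 2937 lower.

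Part of the gain came before E16. From E14 to E16 the largest rises among abundant genes without overlap of the replicates belonged to Ntf3 (log2 fold change 2.43, SE 0.24; n = 3 per age), Sv2c (2.34, SE 0.19), the tachykinin receptor Tacr3 (2.26, SE 0.19), the muscarinic receptor Chrm2 (2.13, SE 0.24) and Aldh1a1 (2.07, SE 0.12). Slc6a3 rose from 10187 ± 858 to 21331 ± 2495 normalized reads, while Th was at 9381 ± 360 and 8927 ± 1781. The largest falls belonged to Fzd10, Pdzrn3, the zinc finger gene St18, Draxin and Cxcr4, at -2.15, -2.02, -2.02, -1.73 and -1.58. Of 44 synaptic genes 27 rose and 0 fell (30 and 0 adjusted over the list alone; camera adjusted p = 2.02e-11, and adjusted p = 0.298 with an estimated correlation), and of 32 ion channel genes 15 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 0.000124, and adjusted p = 0.4 with an estimated correlation). Of 17 dopamine neuron transcription factors 11 fell, with Lmx1b and Foxa2 both at -0.71, and 0 rose (14 and 0 adjusted over the list alone; camera adjusted p = 5.03e-05, and adjusted p = 0.348 with an estimated correlation). Camera called none of the other lists that had enough measured members to be tested in this interval. limma called 3557 of 10781 genes, 1642 higher and 1915 lower at E16, and 222 and 46 of these by at least 2-fold. Rescaling by TMM turned the split to 1870 higher and 1601 lower. Without E14 replicate 2 or 3 it was 1352 higher and 1354 lower or 1367 and 1372.

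From E16 to P0 the largest rises belonged to 2 genes of the astrocyte list. These were the lipid carrier Apoe (log2 fold change 3.18, SE 0.35, n = 3 per age) and the matrix protein Sparcl1 (2.35, SE 0.24). The collagens Col11a2 and Col6a6 and Tmem191c followed. Among neuronal genes Slc18a2, the vesicular monoamine transporter, rose from 8298 ± 305 to 13379 ± 1584 normalized reads and Snap25, of the vesicle fusion machinery, from 5092 ± 262 to 8142 ± 1165. Of 18 genes of dopamine handling 7 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.0151, and adjusted p = 0.486 with an estimated correlation). Of 44 synaptic genes 18 rose and 2 fell (24 and 3 adjusted over the list alone; camera adjusted p = 0.000101, and adjusted p = 0.302 with an estimated correlation), and of 32 ion channel genes 18 rose and 1 fell (18 and 1 adjusted over the list alone; camera adjusted p = 9.28e-06, and adjusted p = 0.302 with an estimated correlation). The largest falls belonged to Cdkn1c, Sinhcaf, the ubiquitin ligase Rnf122, the hypoxia gene Ankrd37 and the transcription factor Bcl11b, at -1.72, -1.67, -1.63, -1.49 and -1.47. Of 17 dopamine neuron transcription factors 12 fell and 0 rose (13 and 0 adjusted over the list alone; camera adjusted p = 9.28e-06, and adjusted p = 0.302 with an estimated correlation). Of 44 ribosomal protein genes 32 fell and 0 rose (35 and 0 adjusted over the list alone; camera adjusted p = 8.54e-11, and adjusted p = 0.302 with an estimated correlation), and of 12 mitochondrially encoded genes 10 fell and 0 rose (11 and 0 adjusted over the list alone; camera adjusted p = 5.59e-05, and adjusted p = 0.302 with an estimated correlation). Of 44 nuclear-encoded oxidative phosphorylation genes 12 fell and 0 rose (11 and 0 adjusted over the list alone; camera adjusted p = 0.000449, and adjusted p = 0.486 with an estimated correlation), and of 32 splicing and RNA editing genes 15 fell and 4 rose (17 and 4 adjusted over the list alone; camera adjusted p = 0.0151, and adjusted p = 0.302 with an estimated correlation). limma called 3605 of 10781 genes, 1816 higher and 1789 lower at P0. Without E16 replicate 2 it was 1799 higher and 1861 lower.

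The course over the 3 ages was not even for some lncRNAs. Miat, a nuclear lncRNA, was at 19079 ± 1291 normalized reads at E14, 12064 ± 1140 at E16 and 30046 ± 237 at P0 (n = 3 per age), and its change after E16 exceeded that before it by 1.98 (SE 0.14) on the log2 scale. Meg3, an imprinted lncRNA, was at 54115 ± 5800, 54500 ± 7369 and 137349 ± 7557, a difference between the intervals of 1.33 (SE 0.20). Snhg11, a neuronal lncRNA, rose in both intervals, by 0.70 (SE 0.09) and 1.46 (SE 0.09). Of 21 neural lncRNAs 8 gained more after E16 than before it and 2 less (9 and 3 adjusted over the list alone; camera adjusted p = 0.00821, and adjusted p = 0.444 with an estimated correlation). From E14 to P0, 6 of these 21 rose and 8 fell (6 and 8 adjusted over the list alone; camera adjusted p = 0.947), with H19 at -2.47. On the log2 scale, which measures relative change, Aldh1a1 and Sv2c gained more before E16, by differences of -1.10 (SE 0.21) and -1.33 (SE 0.33). limma called 1468 genes for a difference between the intervals, 862 with the higher change after E16 and 606 with the higher change before it. These changes are signed, so a smaller fall counts as the higher change. They were not scaled by the length of the intervals, which need not be equal. The count was 976 without E14 replicate 2, 625 without E16 replicate 3 and 887 without P0 replicate 2.

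Single glial genes rose at P0 in the GFP+ fraction, while camera called none of the glial and progenitor lists it tested from E14 to P0. Sparcl1 went from 177 ± 31.2 normalized reads at E14 to 3066 ± 1499 at P0, Apoe from 119 ± 7.50 to 1204 ± 877, Fabp7 from 755 ± 81.2 to 1937 ± 1188 and Ttyh1, a channel protein of radial glia, from 491 ± 19.2 to 1617 ± 374 (n = 3 per age). Their courses differed. Sparcl1 was already at 465 to 664 in the E16 libraries, against 159 to 213 at E14. Apoe was at 76.1 to 150 at E16, against 111 to 126 at E14. P0 replicate 3 held 3.17 times the mean Apoe of the other 2 P0 libraries, 2.61 times their Fabp7, 2.17 times their Sparcl1 and 1.40 times their Ttyh1. Without it these 4 genes were still called, and Ptprz1, a phosphatase of glial progenitors called at a log2 fold change of 0.45, was not (0.20, limma adjusted p = 0.0516). Its adjusted p ran from 0.00560 to 0.0661 over the alternatives, and the call was also lost without E14 replicate 2 (0.0586) or 3 (0.0661). Of 4 astrocyte genes measured 2 rose and 1, Slc1a2, fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.337), and of 8 radial glia and progenitor genes 3 rose and 5 fell, with Vim and Prom1 at -1.62 and -1.84 (3 and 5 adjusted over the list alone; camera adjusted p = 0.332). Of 12 cell division genes 3 rose and 7 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.337), of 4 GABAergic genes 1 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.97), and of 4 oligodendrocyte genes 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.97). The vessel collagen Col4a1 rose by 1.97 (SE 0.18), in a list with too few measured members for a test. Without P0 replicate 3 limma called 5585 genes from E14 to P0 and 3155 from E16 to P0.

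Genes higher in the GFP+ fraction at E14 fell with age in larger number than independent lists would share, and genes lower in it rose in larger number. Of 10699 genes in both gene tables, 475 were higher in GFP+ cells and rose from E14 to P0, where 451 would be shared by independent lists, and 688 were higher in GFP+ cells and fell, where 551 would be. Nr4a2 and Pitx3 were among the latter and Slc6a3 and Aldh1a1 among the former. Of genes lower in GFP+ cells, 595 rose with age, 1.76 times the 338 of independent lists, and 285 fell, against 412. The series covered only genes with a mean of at least 107 normalized reads over its GFP+ libraries. Genes low in GFP+ cells could pass that cut by rising with age, which raises the first of these counts by an amount that was not tested. The sort calls in these counts were made without the block. Across genes, which are not independent replicates, Spearman's rho of the 2 fold changes was -0.133 (jackknife SE 0.0495).

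The circRNA share of reads fell with age. All circRNA reads together came to 1256 ± 113 per 1000000 gene reads at E14, 1051 ± 149 at E16 and 542 ± 35.6 at P0 (mean ± SD, n = 3 per age), and the P0 mean was 0.432 of the E14 mean. An exact permutation test of a trend over the 3 ages, two-sided with 1680 orders, gave p = 0.00238, and E14 against P0 gave an exact p = 0.1, the smallest that 3 against 3 libraries allow. The denominator covers the 10781 genes of that table, so the values are higher than a share of all reads. The GFP− sorted libraries had 673 ± 74.7 per 1000000 over another, longer gene table, which makes that value no control for the series.

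**Figure D3:**
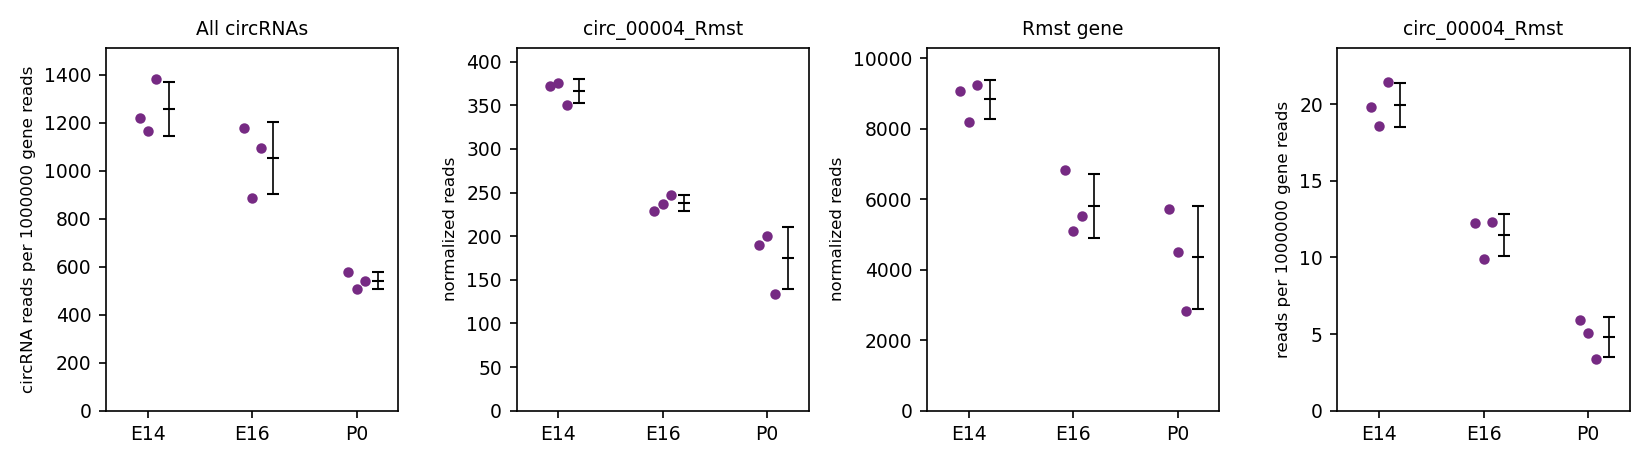
GFP+ cells at E14, E16 and P0, each point a library (3 per age) and bars the mean ± SD, for all circRNA reads per 1000000 gene reads, circ_00004_Rmst normalized reads, Rmst normalized reads and circ_00004_Rmst reads per 1000000 gene reads. The P0 libraries were the lowest for the circRNA total, at 507 to 578 against 1167 to 1382 at E14.

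The circRNA of Rmst fell along with its host gene. circ_00004_Rmst, the most abundant of 21 Rmst circRNAs and the fourth of 7528 circRNAs in the series, was at 366 ± 13.7 normalized reads at E14, 238 ± 9.28 at E16 and 175 ± 35.7 at P0 (n = 3 per age). Its log2 fold change from E14 to P0 was -1.08 (SE 0.15, limma adjusted p = 0.000369), and the authors' deposited table gave -1.08 (SE 0.18, adjusted p = 3.32e-06). The steps to E16 and from E16 were -0.62 and -0.46, with limma adjusted p = 0.503 and 0.228, and the first passed without P0 replicate 3 (adjusted p = 0.0436, the lowest of a range up to 0.996). The Rmst gene (a lincRNA, chromosome 10, 92071037 to 92165170) was at 8838 ± 555, 5814 ± 901 and 4355 ± 1455 normalized reads, and fell from E14 to P0 by 1.08 on the log2 scale (SE 0.19, limma adjusted p = 0.000222). Because the circRNA and gene tables have separate factors, reads per 1000000 gene reads set both on 1 scale. On it circ_00004_Rmst went from 19.9 ± 1.45 over 11.5 ± 1.37 to 4.80 ± 1.30, a P0 to E14 ratio of 0.241 (exact permutation trend p = 0.00119), and Rmst to a ratio of 0.504 (exact permutation trend p = 0.00357). circ_00004_Rmst made up 54.0%, 50.5% and 50.3% of Rmst circRNA reads at the 3 ages. Of 9 Rmst circRNAs tested it alone was called, and circ_00028_Rmst, the next in abundance, went from 122 ± 21.2 at E14 to 38.5 ± 34.0 at P0 (limma adjusted p = 0.0859, and 0.0249 or 0.0312 without P0 replicate 1 or 2, in a range up to 0.261). circ_00563_Rmst passed without P0 replicate 1 (limma adjusted p = 0.0466).

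Single circRNAs changed mostly between E14 and P0. circ_00191_Trpc6 rose from 1.63 ± 1.44 to 48.5 ± 8.64 normalized reads (n = 3 per age; log2 fold change 4.43, SE 0.58), as its host Trpc6 did. circ_00197_Lin28b, from the gene of an inhibitor of let-7 microRNA maturation, went from 27.2 ± 7.30 to 0 reads, 18.3-fold lower against the floor of 3 reads. limma called 52 of 1630 tested circRNAs from E14 to P0, 20 higher and 32 lower, with 309 at an unadjusted p under 0.05, and the authors' deposited table called 38, of which 34 were shared. Without E14 replicates 1, 2 or 3 the count was 9, 15 or 10, without E16 replicate 1 it was 23, and with a pseudocount of 0.5 it was 22, 5 higher and 17 lower. Without P0 replicate 3 the split was 7 higher and 41 lower. With equal circRNA totals the split turned to 32 higher and 23 lower, while the median change over all tested circRNAs moved from -0.36 to -0.21. From E16 to P0 limma called 4 (188 unadjusted; 2 in the authors' deposited table), circ_00197_Lin28b, circ_00366_Pbrm1, circ_00026_Ttc3 and circ_00768, which has no host named. That count was 1 without E14 replicate 1, 2 or 3, 2 without E16 replicate 1 or 2, and 0 without E16 replicate 3. Of 12 alternatives circ_00768 lost its call in 10, among them each library left out (adjusted p up to 0.134), circ_00026_Ttc3 in 8, circ_00366_Pbrm1 in 5 and circ_00197_Lin28b in 1. From E14 to E16 limma called 0 (83 at an unadjusted p under 0.05; 0 in the authors' deposited table, with 65 unadjusted), and 1 without E14 replicate 3 or without P0 replicate 3. Over the 3 ages the moderated F test called 18, and 5, 6 or 7 without E14 replicates 1, 2 or 3. Of the 32 circRNAs called lower from E14 to P0, 28 fell by at least 2-fold. Tests on simulated data found 29.2% of 4-fold changes and none of the smaller ones, so the lack of a call does not show that a circRNA stayed level.

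Some circRNAs moved apart from their host genes between E14 and P0, by an amount that depended on how the circRNA table was scaled. circ_00086_Ezh2 was at 31.0 and 40.0 normalized reads while its host Ezh2, a histone methyltransferase of progenitors, fell by 1.91 on the log2 scale, so that the ratio of circRNA to host rose by 2.26 (SE 0.35, limma adjusted p = 0.00109; n = 3 per age). With circRNA reads on the gene table's scale the rise was 1.26 (SE 0.35, limma adjusted p = 0.0243). The ratio of circ_00197_Lin28b to Lin28b and of circ_00574_Psd3 to Psd3, a neuronal exchange factor, fell as both circRNAs went to 0 reads at P0, from 27.2 and 10.8 normalized reads. limma called 29 of 1558 circRNA to host ratios, 14 higher and 15 lower at P0, with 267 at an unadjusted p under 0.05. On the gene table's scale it called 165, 1 higher and 164 lower, as the median change moved from -0.21 to -0.89. On the separate scales the split was 21 higher and 8 lower with a mean of at least 20, 6 and 14 without P0 replicate 3, and 3 and 8 with the variance trend taken over the ratio. The count was 16, 10 or 12 without E14 replicates 1, 2 or 3. The ratio of circ_00004_Rmst to Rmst was not called on the separate scales of the 2 tables (log2 change -0.01, limma adjusted p = 0.99). It fell by 1.03 (SE 0.16, limma adjusted p = 0.000107) on the gene table's scale.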

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

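The block by the sorted columns' own numbers, the fit without both of their number 1 libraries, the circRNA mean of at least 20, the variance trend over the ratio, the ratio on the gene table's scale and the use of recovered reads for the circRNA total were tests chosen after the data were seen. The sorted count of 5599 genes stayed between 5502 and 5783 with a pseudocount of 4, no filter, TMM, edgeR (5541) and DESeq2 (5502), was 4185 to 5773 leaving out 1 library, and 6679 without both number 1 libraries. With the replicate block by the columns' own numbers, which takes out deviations shared by same-numbered libraries, it was 8466. Beside the changes given with the results, that block changed the call of no other named gene and of no list by camera. For calls adjusted over all genes, it moved the count in either direction by over 1.5 times in no other list but the oligodendrocyte list. That list went from 0 to 1 higher. In the time series the gene counts stayed within 1.5 times under a pseudocount of 4, TMM, the replicate block and, for pairs of ages, a fit of the 6 libraries compared. Deviations of same-numbered libraries in that gene table correlated at -0.113 to 0.245, not over 0.1 for every pair as in the sort, so these samples were taken to share only a number. The block took circ_00028_Rmst from E14 to P0 past the threshold (adjusted p = 0.0339). Leaving out 1 library gave 2706 to 3722 genes from E14 to E16, 2496 to 3660 from E16 to P0, 5212 to 6356 from E14 to P0, 5520 to 6780 over the 3 ages and 625 to 1801 for the difference between the intervals, with fewer samples in each.

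CircRNA counts moved most. With a pseudocount of 0.5 the E14 to P0 count went from 52 to 22. Without a filter the counts were 6 from E14 to E16, 23 from E16 to P0 and 56 over the 3 ages, and with a mean of at least 20 the E16 to P0 count was 2; the causes were not tested. Leaving out 1 library gave 0 to 1 from E14 to E16, 0 to 6 from E16 to P0, 9 to 61 from E14 to P0 and 5 to 20 over the 3 ages. The ratio count of 29 was 165 with circRNA reads on the gene table's scale, 11 with the variance trend over the ratio, 25 to 33 under the other settings, and 10 to 33 leaving out 1 library. The P0 to E14 ratio of the circRNA total was 0.429 to 0.448 with other sums and 0.417 to 0.455 leaving out 1 library. Spearman's rho of sort and age was -0.136 with a mean of at least 50 and -0.154 to -0.104 leaving out 1 library.

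Of the lists called by camera with the preset correlation (15 in the sort, then 3, 8 and 7 from E14 to E16, E16 to P0 and E14 to P0), 0 were called in each comparison with an estimated correlation. Directional fry called 18, 9, 11 and 13 and mixed fry 19, 12, 18 and 18, since fry does not compare a list with other genes. Of 421 results for single genes and circRNAs under 4753 alternatives, 4492 kept their direction and side of the threshold, 244 lost a call, 17 gained one and 0 reversed. A call was lost under at least 1 alternative for 42 of 367 gene results, 12 of 48 circRNA results and 3 of 6 ratios.

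Not run were edgeR and DESeq2 on the time series and circRNA tables, whose values were treated as normalized signal and not as counts, the absent filter for time series genes, since the filter removed none, the labelled replicate block for the sort, and every refit of sorted circRNAs and their ratios or their course over time, for lack of GFP+ values and of a match between tables. Single circRNAs rested on far fewer reads than genes, at 11196 to 33061 circRNA reads per library. The effect of this depth on the calls was not separated from that of the spread between replicates.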

Other observations

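The tests of sequencing depth, of rare circRNAs, of a single P0 library, and of the shift leaving out libraries, with another pseudocount or without one were chosen after the result was seen, as was the way spread was weighed in each of these tests. Known hosts of brain circRNAs went both ways in GFP+ cells from E14 to P0. The postsynaptic scaffold gene Dlgap1 rose from 358 ± 63.3 to 819 ± 63.6 normalized reads (n = 3 per age), the presynaptic gene Rims1 by a log2 fold change of 0.90 (SE 0.09) and the ankyrin gene Ank2 by 0.60 (SE 0.08), while the transcription factor genes Elf2 and Satb1 and Tulp4 were lower at P0, at -1.47, -0.66 and -0.58. Of 32 such hosts 8 rose and 10 fell (8 and 10 adjusted over the list alone; limma camera adjusted p = 0.912). Tulp4, Hdgfl3 and Rims2 gave the 3 most abundant circRNAs of the series, at means of 683, 446 and 304 normalized reads, ahead of circ_00004_Rmst at 260. The libraries held 2363 to 3003 circRNAs above 0 at E14, 2179 to 2851 at E16 and 1356 to 2053 at P0.

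Few genes of dissociation stress were measured in the time series. The heat shock gene Hspa1a and the transcription factor Klf6 rose from E14 to P0, by log2 fold changes of 0.87 (SE 0.14) and 0.56 (SE 0.07), and Klf4 fell from 342 ± 38.0 to 175 ± 52.1 normalized reads (n = 3 per age). Of 6 such genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; limma camera adjusted p = 0.411). Of 44 nuclear-encoded oxidative phosphorylation genes 1, Sdhd, rose and 7 fell, Ndufb9 and Cox7c among them (1 and 5 adjusted over the list alone; camera adjusted p = 0.337).

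CircRNA reads per 1000000 gene reads at P0 were 0.432 of those at E14. Fewer gene reads at P0 were not the source, since the P0 libraries held 1.09 times the gene reads of the E14 libraries (0.687 to 1.86 over single pairs). The loss of rare circRNAs was not the whole source, since the 20 most abundant fell to 0.407 (0.336 to 0.497). Over circRNAs with a mean of at least 2 the P0 to E14 ratio was 0.448, so a part was not excluded. Lower host gene levels could account for a part: over 157 circRNAs with a mean of at least 20, such as circ_00004_Rmst, the median host change was -0.29 (quartiles -0.54 and 0.01) against -1.23 (quartiles -1.69 and -0.63) for the circRNAs, and this host median passed the bound set in advance by less than its spread. Library preparation or RNA quality that differed by age would lower most circRNAs alike, as 89.0% of 163 were, and cannot be told apart from age, because each age was its own set of libraries. A change in circRNA level with neuronal age also stays open and was not tested.

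Some glial transcripts were higher at P0, with Apoe at 1204 and Sparcl1 at 3066 normalized reads. Sparcl1, unlike Apoe, was already higher in every E16 library than in any E14 library. P0 replicate 3 was not the whole source, since 4 of the 5 called astrocyte and radial glia genes were still higher without it. RNA of GFP− cells in the P0 gate is a candidate explanation: 75 genes at least 4-fold lower in GFP+ cells of the sort had a median change from E16 to P0 of 0.34 (quartiles -0.07 and 0.64), with 35 called higher and 6 lower, and 69.3% were higher against 48.4% of all genes. The same genes had a median change of 0.68 from E14 to P0, and Vim, of progenitors, fell to 914 normalized reads. The series covered only genes with a mean of at least 107 normalized reads over its GFP+ libraries. Genes low in GFP+ cells at E14 could pass that cut by rising later, which favours rises among the 75. How much of the shift came from this was not tested. How many GFP− cells passed the P0 gate is not known, since the series held no GFP− libraries. A rise of these transcripts within the GFP+ neurons stays open and was not tested.

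The normalized values of circRNAs were shifted down at P0, with a median log2 change from E14 of -0.36 over 1630 circRNAs. Fewer circRNA reads combined with a pseudocount of 1 could lower rare circRNAs most. It was not the whole source for the abundant ones: over 163 circRNAs with a mean of at least 20, such as circ_00004_Rmst, the median was -0.28 (quartiles -0.73 and 0.35), past the bound set in advance by more than its SE over circRNAs of 0.0782. It was -0.29 with a pseudocount of 0.5, and the median log2 ratio of the means, without any pseudocount, was -0.24 (-0.30 to -0.15 leaving out 1 library). The margin was narrow between libraries, since leaving out 1 gave medians of -0.31 to -0.19, some of which fell short of that bound. For the 1467 with a mean of at least 2 and under 20 the median of -0.36 became -0.49 with a pseudocount of 0.5, and the median log2 ratio of the means, which needs no pseudocount, was -0.16 (-0.26 to -0.08 leaving out 1 library). That lies between the bounds set for the test, so for these the pseudocount and a shift cannot be told apart. With equal circRNA totals the median over all 1630 was -0.21, so the scaling stays open for a part, as does a change with age, which was not tested.

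The 6 libraries of a comparison of 2 groups form 10 splits, too few for a share under 0.05. In the sort 1 of 10 splits, the real one, called as many genes as observed, 5599 against 0 in the highest other, those that part the same-numbered libraries included, and 1 of 10 each did so for E14 to E16 (3557 against 0), E16 to P0 (3605 against 0) and E14 to P0 (6003 against 0). For circRNAs it was 10 of 10 from E14 to E16 (0 in all; at an unadjusted p under 0.05 limma had 83 for the real split, and the authors' deposited table had 65, with 0 adjusted), 1 of 10 from E16 to P0 (4 against 0), 1 of 10 from E14 to P0 (52 against 0) and 1 of 10 for the ratio (29 against 1). Over the 3 ages 1 of 100 splits of the 9 libraries, the real one, called as many genes (6432 against 2723). For circRNAs it was also 1 of 100 (18 against 6), though the real count of 18 was 5, 6 or 7 without E14 replicates 1, 2 or 3. These shares are under 0.05, which makes chance less likely without excluding it. They also take the libraries as independent samples, which the sources do not settle. For the difference between the intervals 2 of 100 splits called as many as the observed 1468 genes, the other calling 3749. That split set all 3 P0 libraries as its middle group between mixed E14 and E16 libraries, so it follows the difference between P0 and the earlier ages.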
